A study of Homo sapiens with 18 samples.

How the data were processed

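RNA of HEK293T cells that expressed YTHDF1-ADAR, YTHDF2-ADAR or YTHDF3-ADAR was sequenced as total RNA and as polysome RNA, with 3 libraries in each of the 6 groups and 18 in all. Libraries were made with a strand-specific kit after removal of ribosomal RNA. Per the submitters' processing notes, reads were handled with STAR 2.7.7, featureCounts 2.0.1 and DESeq2 on GRCh38 (hg38), while the strand setting, the annotation release and the DESeq2 version are not given in the sources used here. The labels do not say whether the replicates are separate cultures, so they may be technical.

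The deposited count table holds the count of reads per gene and library, with no normalization, for 60675 human gene rows and 1 row that does not name a human gene. The deposited comparison table holds the signal (baseMean), the log2 fold change and the p-value of a comparison that is not named. Its signal equals the mean of normalised counts over all 18 libraries. The authors' editing tables hold, per gene and construct, the number of sites and an editing score for total and for polysome RNA, with 1 value over the replicates. The score never exceeds the number of sites, and score divided by sites is reported here as editing per site in percent. The deposited column of editing change is the natural log of the odds ratio of that share, whatever its header says, with a largest difference of 5.62e-08 from the recomputed value. How sites were called, how replicates were combined and which test gave the authors' adjusted p-value is not given in the sources used here. Sequencing depth behind the scores is unknown, so no interval is given for them. Gene symbols came from the deposited comparison table, and for the 93 gene IDs absent from it the name table gave no symbol.

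Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 6 groups with its minimum count of 10, which left 26804, and libraries were scaled with TMM factors. A single quasi-likelihood fit with robust dispersion held the 6 group means. Tests were polysome against total RNA in each line, the difference of that change between lines, and total RNA between lines, each with Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change divided by the root of its F statistic. Gene levels are CPM, counts scaled to a common library total, with SD over n = 3 libraries. Depth ran from 42.7e6 to 67.5e6 counts per library. Read counts without molecular identifiers are not independent molecules, so the error stated covers the libraries compared and no more.

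Gene lists were tested with camera in limma 3.58.1 with an inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast, and the difference between lines also with fry and the replicate block. Lists with fewer than 5 tested members had no set test. Gene lists, the planned tests and alternatives, and the rule for named genes were fixed before the data were examined. By that rule, the genes named are the 12 highest and 12 lowest by mean fold change among genes with a mean log2 CPM of at least 2 called in the same direction in all 3 lines, up to 4 members of each list, the 10 highest and 10 lowest per contrast of total RNA, and YTHDF1, YTHDF2, YTHDF3, ADAR, ADARB1 and ADARB2. For editing they are the 10 highest polysome scores, up to 10 largest changes among the authors' calls and the 5 genes with most sites per construct. The genes of the brain plot and those named in the closing section for repeated editing calls or zinc finger editing were chosen after their values were seen. Set tests of the difference between lines, by camera or fry, were not in the plan fixed beforehand. Nor were the tests of edited genes per list, the permutation test of library pairs and the McNemar test. Some items are withheld and are not reported here.

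The planned editing tests needed values per library, which the tables do not hold, so only the authors' own calls are given. Sites shared between constructs could be counted by gene only, with a one-sided Fisher exact test. Edited protein-coding genes were compared with 10000 random lists of unedited genes matched on expression in 20 bins. Same-numbered polysome and total RNA libraries of a line were correlated after removing group means, and all 9 pairs had r above 0.1. Some libraries of different number were at least as close. YTHDF3-ADAR polysome replicate 2 had r of 0.51 with total RNA replicate 3 and 0.36 with replicate 2. YTHDF1-ADAR polysome replicate 1 had r of 0.28 with total RNA replicate 2 and 0.25 with replicate 1. The number thus does not establish pairing, and it was used as a block within a line only as an alternative. Replicate numbers did not pair samples across lines, although YTHDF1-ADAR replicate 3 and YTHDF2-ADAR replicate 2 went together. Pairwise comparison of libraries within groups found no duplicates, with a chi-square per degree of freedom of at least 6.955. The fit was tested on simulated data with known changes in 200 genes. Each gene was drawn independently around its mean over all 18 libraries, with no other difference between groups and no shift shared by libraries. Alternatives were DESeq2 1.42.0, DESeq2 size factors, no normalization factor, other filters, a fold threshold, the replicate block, fits of the compared libraries alone, and leaving out each library. For edited genes, leaving out a library used fold changes from a fit with fixed dispersion. Leaving out YTHDF3-ADAR replicate 1, leaving out YTHDF1-ADAR replicate 3 and YTHDF2-ADAR replicate 2, leaving out genes low in those 4 libraries, comparing list medians under each scaling counting list members in fits of the compared libraries and a term for the 4 libraries that go together were chosen after seeing the data. Gene lengths in the deposited table are those of gene models.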

Results

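RNA was sequenced from HEK293T cells, a human embryonic kidney line, that expressed YTHDF1, YTHDF2 or YTHDF3 fused to an ADAR adenosine deaminase. The YTHDF proteins bind methylated adenosines (m6A) in mRNA, and the fused deaminase changes adenosines near the bound site so that they read as G, which marks the transcripts each protein has met. Expression of the fusion was induced with 1 µg/mL doxycycline for 24 h, and ribosomes were held on mRNA by 10 min of cycloheximide at 100 µg/mL. Total RNA and the RNA of pooled polysome fractions of a sucrose gradient were each sequenced in 3 libraries per construct, giving 6 groups and 18 libraries. Libraries held between 42.7e6 and 67.5e6 counts over 60675 human gene rows, and 26804 genes passed the expression filter, of which 15675 were protein coding. No library without a fusion construct was among them, so the constructs were compared with each other.

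The genes of the fusion proteins came first, since they check the labels. YTHDF1 stood at 392 ± 46.5 CPM (counts scaled to a common library total; mean ± SD, n = 3) in total RNA of YTHDF1-ADAR cells, against 83.2 ± 5.11 in YTHDF2-ADAR and 68.0 ± 9.92 in YTHDF3-ADAR cells. YTHDF2 stood at 275 ± 14 CPM in YTHDF2-ADAR cells, against 147 ± 10.2 and 129 ± 16.1 in YTHDF1-ADAR and YTHDF3-ADAR cells. YTHDF3 reached 76.7 ± 9.73 CPM in YTHDF3-ADAR cells, 0.46 ± 0.12 (log2, ± SE) above YTHDF1-ADAR cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0168) and 0.58 ± 0.12 above YTHDF2-ADAR cells (adjusted p = 0.00422), so each target was highest in its own line in total RNA. ADARB1, which encodes the deaminase ADAR2, differed most, at 1460 ± 326 CPM in YTHDF3-ADAR, 247 ± 17.7 in YTHDF1-ADAR and 38.9 ± 1.55 in YTHDF2-ADAR total RNA. ADAR, which encodes ADAR1, lay at 319 ± 5.71, 280 ± 13.3 and 305 ± 9.46 CPM in the same lines, with no call between any of them, and ADARB2 was too low to test. ADARB1 was highest in YTHDF3-ADAR cells, whose YTHDF target rose least, so its level did not follow the rise of the YTHDF genes. On polysomes YTHDF3 overlapped between YTHDF3-ADAR and YTHDF1-ADAR libraries. The deposited annotation does not separate counts of a transgene from those of the endogenous gene.

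**Figure D1:**
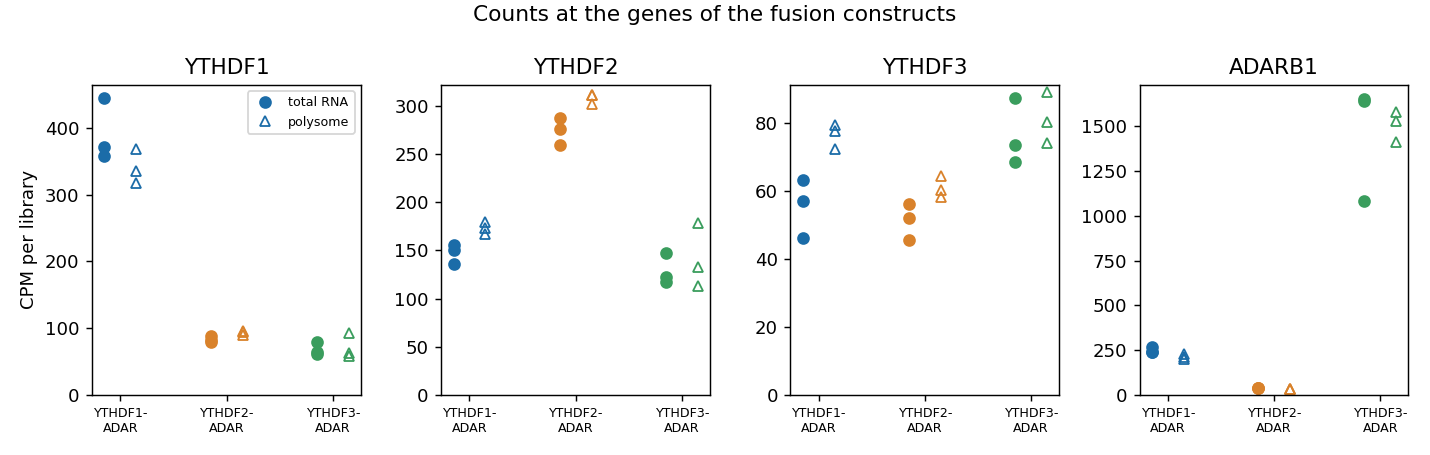
CPM per library at YTHDF1, YTHDF2, YTHDF3 and ADARB1 (y axis) by construct (x axis), with filled circles for total RNA and open triangles for polysome RNA. In total RNA each YTHDF gene was highest in the line named for it. On polysomes YTHDF3 overlapped (74.3 CPM in YTHDF3-ADAR replicate 3 against 79.4 and 77.7 in YTHDF1-ADAR replicates 1 and 3). ADARB1 was highest in YTHDF3-ADAR cells at 1460 CPM in total RNA.

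Polysome RNA was richer in protein-coding transcripts than total RNA. Protein-coding genes took 63.0% ± 6.86 (SD, n = 3) of counts in total RNA of YTHDF1-ADAR cells and 89.7% ± 0.542 in their polysome RNA, 65.5% ± 4.42 and 89.6% ± 0.885 in YTHDF2-ADAR cells, and 72.8% ± 1.80 and 90.1% ± 0.730 in YTHDF3-ADAR cells. Small structured RNAs of the class misc RNA, such as the signal recognition particle RNA, fell from 9.96%, 10.6% and 12.2% of counts to 0.690%, 0.717% and 0.754%. Total RNA libraries differed between lines, since mitochondrial ribosomal RNA took 2.7% ± 0.805 and 2.29% ± 0.304 of counts in YTHDF1-ADAR and YTHDF2-ADAR cells and 0.340% ± 0.0778 in YTHDF3-ADAR cells. Ribosomal RNA had been removed from the libraries, so counts of ribosomal RNAs, here and below, also depend on how complete that removal was. Replicate 1 of YTHDF1-ADAR total RNA held 25.65% of its counts in long noncoding RNAs, against 13.8% and 15.45% in the other replicates.

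The polysome comparison asked which transcripts were carried by ribosomes in each line. Several abundant noncoding RNAs were lowest on polysomes in all 3 lines. RN7SK, a nuclear RNA that holds back transcription elongation, fell by 5.12, 5.07 and 4.75 on the log2 scale (SE 0.17 in each line) in YTHDF1-ADAR, YTHDF2-ADAR and YTHDF3-ADAR cells. BCYRN1, a short noncoding RNA, fell, with log2 changes of -5.72, -5.26 and -5.12 (SE 0.21), and RN7SL2, the RNA of the signal recognition particle, went from 40300 ± 1500 CPM in total RNA to 1950 ± 444 on polysomes in YTHDF1-ADAR cells (mean ± SD, n = 3). MT-RNR1, the small mitochondrial ribosomal RNA, fell by 6.06 ± 0.58, 5.75 ± 0.58 and 2.72 ± 0.50. The other named RNAs among the 12 lowest were the 7SK row that overlaps RN7SK, 4 copies of 7SK (RN7SKP71, RN7SKP203, RN7SKP255 and RN7SKP80), the signal recognition particle copies RN7SL4P and RN7SL5P, and RNY3, with mean log2 fold changes over the 3 lines from -5.64 to -4.38. Reads of such near-identical copies cannot be assigned to 1 locus, so their levels are uncertain.

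Lists of untranslated or organellar RNAs were fixed before the data were examined, and the share of their members that fell differed. All 13 mRNAs encoded in the mitochondrial genome, which mitochondrial ribosomes translate, were lower on polysomes in each line, with medians of -2.34, -2.30 and -2.36 (log2). MT-ND2, a complex I subunit, fell by 3.79, 3.89 and 3.77 (SE 0.38), and MT-ATP8, an ATP synthase subunit, by 3.58, 3.40 and 3.10. Among 33 tested structured noncoding RNAs, 27, 27 and 25 were lower, and adjusted over the list alone 28, 28 and 26. YTHDF3-ADAR cells also had 1 member higher. Of 14 tested nuclear long noncoding RNAs, 5 fell in each line and 9 were not called, among the former TERC, the telomerase RNA, by 2.81, 2.62 and 2.84, and MALAT1, a nuclear speckle RNA, by 0.70, 0.75 and 0.70. Of 25 snoRNA host genes, whose introns carry small nucleolar RNAs, 11, 12 and 16 fell and 14, 13 and 9 were not called, with falls such as SNHG19 by 1.86, 1.99 and 2.61 and SNHG5 by 1.64, 1.65 and 2.47. The competitive set test camera with its preset correlation placed all 4 lists below the other genes in each line, with adjusted p-values (Benjamini-Hochberg) no higher than 0.00220. Without normalization factors the median of all genes moved from 0.03, 0.03 and -0.05 to 0.46, 0.40 and 0.25. That of the nuclear long noncoding RNAs turned from -0.38 to 0.06 in YTHDF1-ADAR cells, while the other 3 lists stayed below 0 in each line. With an estimated correlation, the structured RNAs of YTHDF2-ADAR cells alone passed (adjusted p = 0.0461 with an estimated correlation), and the others of these lists gave adjusted p-values from 0.073 to 0.253 with an estimated correlation.

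The mRNAs of mitochondrial proteins and histones stood at the other end. Of 73 nuclear-encoded subunits of the respiratory chain, 50, 47 and 30 were higher on polysomes in YTHDF1-ADAR, YTHDF2-ADAR and YTHDF3-ADAR cells and none was lower, with medians of 0.39, 0.38 and 0.30. SDHD, an anchor of complex II, rose by 0.61, 0.65 and 0.69 (SE 0.08), and COX5B, a subunit of complex IV, by 0.59, 0.56 and 0.49 (SE 0.11). Of 64 mitochondrial ribosomal proteins, 39, 38 and 25 rose, and MRPL13 rose by 0.63, 0.53 and 0.73 (SE 0.10). Adjusted over the list alone, 61, 60 and 44 respiratory chain genes and 57, 54 and 33 mitochondrial ribosomal genes were higher. Of 52 tested replication-dependent histone genes, whose mRNAs end in a stem-loop in place of a poly(A) tail, 22, 24 and 28 rose, among them H2AC4 by 0.69, 0.67 and 0.95 (SE 0.15) and H4C4 by 0.65, 0.74 and 0.85 (SE 0.20). Proteasome subunits rose in 10, 16 and 12 of 31 cases, such as PSMA3, a core subunit, by 0.46, 0.44 and 0.59. Endoplasmic reticulum folding genes rose in 13, 12 and 10 of 35 cases, such as SPCS3, a signal peptidase subunit, by 0.62, 0.54 and 0.85, and 1, 0 and 1 fell. Translation initiation factors went both ways: 9, 8 and 7 of 31 rose, among them EIF4E, the cap-binding factor, by 0.54, 0.47 and 0.46, while 2 and 1 fell in YTHDF1-ADAR and YTHDF2-ADAR cells. EIF3A, a scaffold subunit of the initiation factor eIF3, fell by 0.99 ± 0.25 in YTHDF1-ADAR cells and by 0.78 ± 0.25 in YTHDF2-ADAR cells, and stood at -0.04 ± 0.25 in YTHDF3-ADAR cells. With the replicate block, which pairs same-numbered libraries within a line, 58, 56 and 44 mitochondrial ribosomal genes, 59, 58 and 45 respiratory chain genes, 38, 40 and 37 histone genes, 24, 22 and 20 proteasome genes, 21, 19 and 14 folding genes and 18, 16 and 10 initiation factors were higher. With it 3, 0 and 2 folding genes, 4, 1 and 1 initiation factors and 0, 0 and 1 mitochondrial ribosomal genes were lower. All 6 lists passed camera with the preset correlation in each line, and none did with an estimated correlation, where the lowest value was adjusted p = 0.139 with an estimated correlation for both mitochondrial lists in YTHDF2-ADAR cells.

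**Figure D2:**
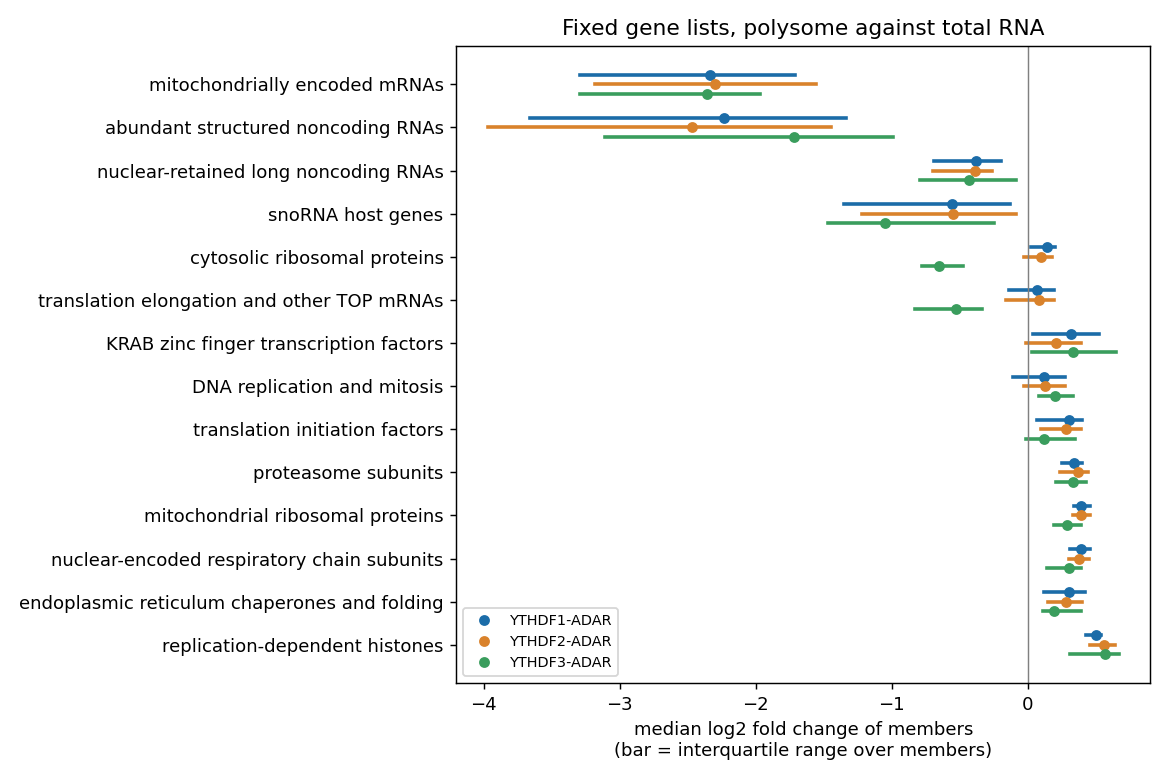
Median log2 fold change of polysome against total RNA over the tested members of each gene list fixed before the data were examined (x axis), for each construct (colour), with bars for the interquartile range over members. Mitochondrially encoded mRNAs had medians near -2.3 in all 3 lines, while cytosolic ribosomal proteins stood at -0.65 in YTHDF3-ADAR cells against 0.14 and 0.10 in the others.

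In all, 2481 genes were higher and 3193 lower on polysomes in YTHDF1-ADAR cells, 1799 and 2424 in YTHDF2-ADAR cells, and 2147 and 3245 in YTHDF3-ADAR cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). With the replicate number as a block, a pairing that the labels do not state, the counts were 5012 and 4831, 4148 and 4010, and 3640 and 5390. The balance depended on scaling: without normalization factors 10894 genes were higher and 1527 lower, 9093 and 1364, and 6788 and 1668, so that higher calls outnumbered lower ones in each line. With DESeq2 size factors YTHDF3-ADAR cells had 2798 higher and 2838 lower. In fits of the compared libraries alone, edgeR called 2943 and 4327 genes in YTHDF1-ADAR cells, 3766 and 4088 in YTHDF2-ADAR cells, but 0 and 219 in YTHDF3-ADAR cells, where 4438 genes had an unadjusted p under 0.05 and DESeq2 over all libraries called 3224 and 3188. Few genes rose at least 2-fold (41, 14 and 74), while 1919, 1532 and 1701 fell that far. The lists overlapped: 993 genes rose and 1758 fell in all 3 lines, against 13.3 and 35.0 if the lists were independent, and no gene was called in opposite directions (2 were with the replicate block). Fold changes across genes, which are not independent replicates, had Pearson's r of 0.85 between YTHDF1-ADAR and YTHDF2-ADAR, 0.80 between YTHDF1-ADAR and YTHDF3-ADAR, and 0.78 between YTHDF2-ADAR and YTHDF3-ADAR. The 12 genes with the highest mean fold change included SNX10, an endosomal sorting protein (0.78, 0.75 and 0.88), ARL6, a ciliary GTPase (0.83, 0.63 and 0.90), GOLT1B, a Golgi transport protein (0.83, 0.73 and 0.81), DYNLT3, a dynein light chain (0.78, 0.69 and 0.78), and TWSG1, a secreted regulator of bone morphogenetic proteins (0.70, 0.62 and 0.77). The others were H2AC4, H4C4, the antisense RNA SPCS3-AS1 and the processed pseudogenes UBE2SP2, PPIAP29, SUMO2P1 and SUMO2P21, whose reads cannot be told from those of their parent genes. The authors' deposited table of a polysome comparison does not name its contrast. Its log2 fold changes had Pearson's r of 0.999 across genes with those of YTHDF1-ADAR cells, and 0.853 and 0.803 with the other lines, and it listed 2649 genes higher and 3477 lower. Counts also moved with single libraries: without YTHDF3-ADAR polysome replicate 2, 886 genes were higher and 1941 lower in that line, and without its total RNA replicate 1, 3936 and 3139.

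The mRNAs of the cytosolic ribosome were lower on polysomes in 2 of the 3 YTHDF3-ADAR library pairs. Of 78 cytosolic ribosomal protein genes, 60 were lower on polysomes in YTHDF3-ADAR cells (72 adjusted over the list alone), with a median of -0.65, while 2 were higher and 2 lower in YTHDF1-ADAR cells (median 0.14) and 2 were lower in YTHDF2-ADAR cells (median 0.10). RPS2 fell in all lines, by 1.24 ± 0.19, 1.21 ± 0.19 and 1.76 ± 0.20, as did RPSA, by 0.69, 0.64 and 1.42. Of 17 elongation factors and other mRNAs with a terminal oligopyrimidine (TOP) start, 10 fell in YTHDF3-ADAR cells, against 1 in YTHDF1-ADAR cells and none in YTHDF2-ADAR cells, where 1 rose. TPT1 fell by 1.18 ± 0.16, EEF1G by 1.06 ± 0.16 and EEF2, which moves the ribosome along the mRNA, by 0.92 ± 0.22 in YTHDF3-ADAR cells. In YTHDF1-ADAR cells these 3 genes stood at -0.34, -0.18 and -0.40 with no call. Camera with the preset correlation gave adjusted p = 2.09e-18 for the ribosomal proteins and 0.000107 for the TOP list in YTHDF3-ADAR cells, and both had adjusted p = 0.312 with an estimated correlation. In a fit of the YTHDF3-ADAR libraries alone, edgeR called 1 of the 78 ribosomal protein genes and 0 of the TOP list lower, with medians of -0.63 and -0.52. The 3 YTHDF3-ADAR replicates differed: relative to all protein-coding genes, the ribosomal protein median of same-numbered polysome and total RNA libraries was -0.07 in replicate 1, -1.30 in replicate 2 and -0.68 in replicate 3, while the 6 pairs of the other lines lay between -0.11 and 0.14. An exact two-sided permutation test of the 3 pairs against the other 6 gave p = 0.0238 over 84 splits, and 0.0952 after Benjamini-Hochberg adjustment over 4 lists. The 4 were the ribosomal protein, TOP, mitochondrial ribosomal and respiratory chain lists. The adjustment thus does not cover the choice of these from all lists. The library pairs follow the replicate number, and the labels do not state such a pairing.

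**Figure D3:**
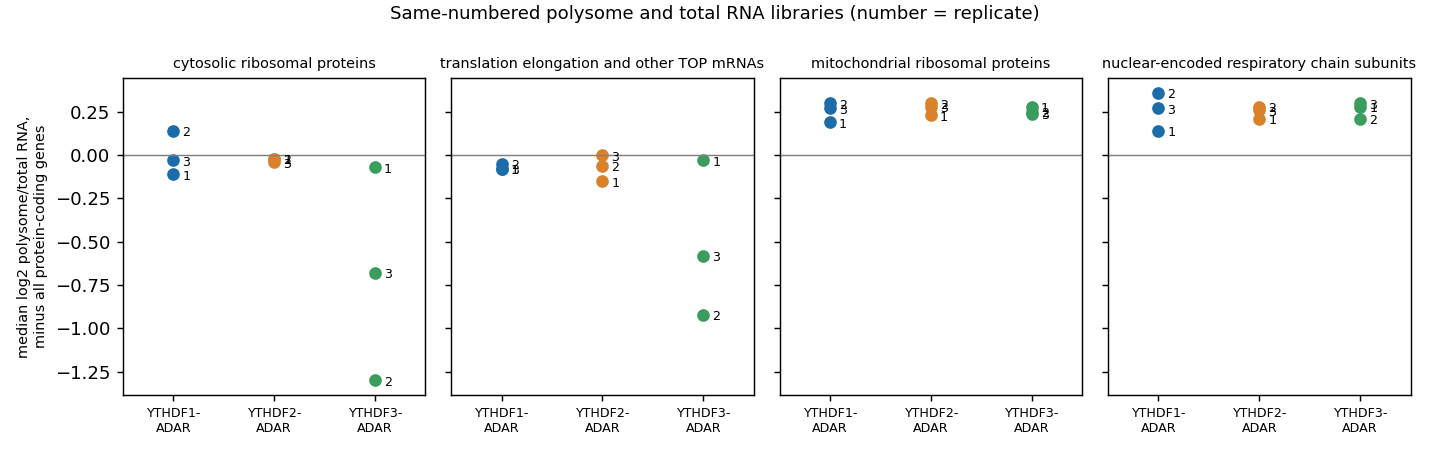
Median log2 ratio of polysome to total RNA over the genes of 4 lists, minus the median over all protein-coding genes (y axis), for each same-numbered pair of libraries by construct (x axis; numbers mark the replicate). For cytosolic ribosomal proteins, YTHDF3-ADAR replicates 2 and 3 stood at -1.30 and -0.68 and the other 7 pairs between -0.11 and 0.14.

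The test of the difference itself asked whether polysome association differed between lines. No single gene passed it: edgeR called 0 genes for YTHDF2-ADAR minus YTHDF1-ADAR, for YTHDF3-ADAR minus YTHDF1-ADAR and for YTHDF3-ADAR minus YTHDF2-ADAR, with 166, 877 and 801 genes at an unadjusted p under 0.05, and DESeq2 called 0, 1 and 0. The ribosomal protein median differed by -0.73 between YTHDF3-ADAR and YTHDF1-ADAR and by -0.71 between YTHDF3-ADAR and YTHDF2-ADAR. Set tests of the differences between lines were not in the plan fixed beforehand. Camera with the preset correlation gave adjusted p = 5.83e-70 and 8.14e-62 for these differences, but adjusted p = 0.226 and 0.237 with an estimated correlation, and limma's fry test with the replicate block gave adjusted p = 0.279 and 0.284. The TOP list differed by -0.57 and -0.61, and snoRNA host genes by -0.29 and -0.28, while structured noncoding RNAs stood 0.37 and 0.32 higher. Each passed camera with the preset correlation (adjusted p no higher than 0.00177), and none did with an estimated correlation (adjusted p = 0.226 or higher with an estimated correlation). By fry with the block, the list of integrated stress response mRNAs with upstream ORFs alone moved on balance one way, downward, in YTHDF3-ADAR against YTHDF1-ADAR cells (adjusted p = 0.00959) and against YTHDF2-ADAR cells (adjusted p = 0.0294), with a median of -0.13 in each and no member called, while camera gave adjusted p = 0.619 and 0.869. Leaving out YTHDF3-ADAR replicate 1 of both fractions, chosen after the data were seen, gave 265 genes against YTHDF1-ADAR cells (87 higher, 178 lower), of which 62 were ribosomal proteins, all lower. The pair left out is the one without the fall of these genes, so this count depends on the pattern itself and is no test of it. In simulated counts, the difference test recovered 5.97% of genes changed 1.5-fold, 35.8% of those changed 2-fold and 89.4% of those changed 4-fold. The simulated genes were independent and lacked the shifts that real libraries shared, so these shares may not hold for the real data.

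Among the other lists on polysomes, KRAB zinc finger genes, many of which silence transposable elements, rose in 7, 1 and 13 and fell in 2, 1 and 3 of 101 cases, with medians of 0.32, 0.21 and 0.33, and ZNF124 fell in all 3 lines by 1.03, 0.98 and 1.62. Without YTHDF3-ADAR pair 1, 57 KRAB genes were higher and 8 lower in that line, with a median of 0.61. Selenoprotein genes rose in 5, 5 and 4 and fell in 2, 1 and 1 of 22 cases, with SELENOW falling by 1.39, 1.40 and 1.75. Cholesterol synthesis genes rose in 3, 2 and 5 and fell in 1, 0 and 1 of 24 cases, and replication and mitosis genes rose in 6, 5 and 6 and fell in 1, 0 and 0 of 34. P-body and stress granule genes rose in 4, 2 and 5 and fell in 4, 1 and 3 of 34 cases, with ATXN2 falling by 0.62, 0.48 and 0.50. Interferon-stimulated genes rose in 2, 1 and 2 and fell in 3, 2 and 3 of 25 cases, and cytosolic chaperones rose in 0, 0 and 4 and fell in 1, 0 and 0 of 24. The p53 targets rose in 1, 0 and 3 of 20 cases, upstream ORF mRNAs of the integrated stress response in 1, 1 and 1 of 14, and neither list had a member lower. Genes of m6A writers, erasers and readers rose in 1, 1 and 3 of 22 cases and fell in 0, 0 and 1, and immediate early genes rose in 1, 0 and 0 of 29 cases and fell in 0, 0 and 1. The 2 tested ADAR genes did not pass in any line. The replicate block raised most of these counts. With it 20, 9 and 20 KRAB genes were higher and 5, 5 and 9 lower, 13, 10 and 9 selenoprotein genes higher and 2, 2 and 1 lower, 12, 10 and 9 cholesterol genes higher and 2, 1 and 2 lower, and 12, 11 and 9 replication genes higher and 2, 0 and 3 lower. P-body genes were then higher in 10, 5 and 11 and lower in 6, 4 and 6 cases, interferon-stimulated genes in 4, 4 and 4 and 5, 3 and 5, and cytosolic chaperones in 4, 2 and 10 and 3, 0 and 3. The p53 targets had 8, 6 and 6 higher and 1, 0 and 0 lower, the stress response list 6, 4 and 4 and 1, 1 and 3, the m6A genes 5, 3 and 4 and 0, 0 and 2, and immediate early genes 5, 4 and 1 and 1, 0 and 4. Camera with the block and the preset correlation also called the p53 targets upward in each line (adjusted p = 0.0189, 0.0168 and 0.0294) and the m6A genes in YTHDF3-ADAR cells (adjusted p = 0.0341). Camera with the preset correlation placed the KRAB, selenoprotein and cholesterol lists above other genes in all 3 lines, the replication list in YTHDF2-ADAR and YTHDF3-ADAR cells and the cytosolic chaperones in YTHDF3-ADAR cells. All of these calls were lost with an estimated correlation, where the lowest value was adjusted p = 0.139 with an estimated correlation for selenoproteins in YTHDF2-ADAR cells. Among markers of other cell types, 1, 2 and 1 of 8 tested fibroblast genes fell, 1, 1 and 0 of 3 squamous epithelial genes rose, and 1, 0 and 1 of 6 blood genes fell.

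Total RNA of the 3 lines differed in single genes and in groups. CCND1, which encodes the cell cycle regulator cyclin D1, stood at 103 ± 0.540 CPM in YTHDF2-ADAR cells, 15.3 ± 1.26 in YTHDF1-ADAR and 28.2 ± 8.29 in YTHDF3-ADAR cells (mean ± SD, n = 3). NPTX2, a neuronal pentraxin, was highest in YTHDF1-ADAR cells at 249 ± 98.8 CPM, against 23.4 ± 0.233 and 28.2 ± 5.70. TNFRSF10D, a decoy receptor for the death ligand TRAIL, was almost absent from YTHDF2-ADAR cells (0.201 ± 0.0935 CPM, against 9.44 ± 2.02 and 7.54 ± 2.49), as was OXCT1, an enzyme of ketone body use (1.03 ± 0.411, against 12.7 ± 1.57 and 14.6 ± 1.38). YTHDF3-ADAR cells had more MAP7D2, a microtubule-binding protein (22.3 ± 4.59 CPM, against 1.31 ± 0.167 and 0.387 ± 0.0969), TGFBR2, a receptor for transforming growth factor beta (11.5 ± 2.53, against 0.889 ± 0.184 and 1.06 ± 0.152), and the zinc finger gene ZNF462 (20.3 ± 2.95, against 1.66 ± 0.0914 and 1.78 ± 0.271). CRABP2, IGF2 and G0S2 were also among the highest in YTHDF3-ADAR cells, but their replicates spread widely (51.5 ± 36.0, 40.9 ± 31 and 13 ± 9.61 CPM). The lowest were ribosomal and mitochondrial RNAs, such as MT-RNR1 at 1060 ± 261 CPM against 13900 ± 6000 and 11500 ± 2770, and the 5.8S ribosomal RNA rows, of which RNA5-8SN4 stood at 112 ± 127 CPM against 2230 ± 1580 and 1550 ± 729. Ribosomal RNA had been removed before sequencing, so for ribosomal RNAs a difference between lines and a difference in that removal cannot be told apart.

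By group, 9 of 13 mitochondrially encoded mRNAs were lower in YTHDF3-ADAR cells than in either other line, with medians of -1.21 against YTHDF1-ADAR and -1.03 against YTHDF2-ADAR cells. Of 101 KRAB zinc finger genes, 44 were lower and 7 higher in YTHDF3-ADAR than in YTHDF2-ADAR cells (56 lower and 8 higher adjusted over the list alone), 13 lower and 10 higher against YTHDF1-ADAR cells, and 11 higher and 3 lower in YTHDF2-ADAR than in YTHDF1-ADAR cells. Of 25 tested interferon-stimulated genes, 10 were higher and 1 lower in YTHDF3-ADAR than in YTHDF1-ADAR cells and 9 higher and 1 lower than in YTHDF2-ADAR cells. For this list camera with the preset correlation gave adjusted p = 0.0428 and 0.076, or 0.733 and 0.723 with an estimated correlation. Endoplasmic reticulum folding genes were lower in 12 and 8 and higher in 1 and 1 of 35 cases, cytosolic chaperones lower in 2 and 5 and higher in 0 and 1 of 24, and P-body and stress granule genes lower in 4 and 7 and higher in 1 and 0 of 34. Without normalization factors, which moved the median of all genes from 0.02 to 0.25 against YTHDF1-ADAR and from 0.02 to 0.20 against YTHDF2-ADAR cells, the medians of the KRAB genes (-0.20 to 0.02) and of the P-body list (-0.17 to 0.07) changed sign in the comparison with YTHDF1-ADAR cells, while the mitochondrially encoded mRNAs stayed lower, at -0.96 and -0.83. Markers of other cell types rose as well, with 3 of 8 fibroblast genes, 2 and 1 of 3 squamous epithelial genes and 3 of 6 blood genes, such as HBA2 at 10.7 ± 3.34 CPM against 4.01 ± 0.673 and 3.55 ± 0.945. Camera with the preset correlation called 2, 13 and 12 lists in the 3 contrasts, and none with an estimated correlation (adjusted p = 0.628 or higher). Gene counts were 146 higher and 344 lower in YTHDF2-ADAR against YTHDF1-ADAR cells, 3109 and 1747 in YTHDF3-ADAR against YTHDF1-ADAR cells, and 4085 and 2028 in YTHDF3-ADAR against YTHDF2-ADAR cells (edgeR, Benjamini-Hochberg adjusted p under 0.05). In fits of the compared libraries alone they were 969, 347 and 1496 in all, and without normalization factors 326, 7314 and 7147. YTHDF1-ADAR replicate 3 and YTHDF2-ADAR replicate 2 went together across these lines (r of 0.67 in total and 0.58 in polysome RNA after removing group means), and stood apart on the principal component with 10.4% of the variance. With a term for these 4 libraries, chosen after the data were seen, the first contrast had 518 calls against 490, and without them 68. YTHDF3-ADAR total RNA replicate 1 stood apart from replicates 2 and 3 on the first principal component (-4.40 against 87.9 and 87.7, with 34.9% of the variance). Without it the counts of called genes rose from 4856 to 10038 and from 6113 to 11327.

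The deposited editing tables ask which genes each fusion protein had marked, and whether the marks differed between polysome and total RNA. They give 1 score per gene and fraction over all replicates, with no error or depth, so the calls quoted here are the authors' own. No library without a fusion was among them. A gene called edited by a construct is thus one listed for that line, and other sources of its editing are not separated. YTHDF1-ADAR had edited 6858 genes at 43036 sites, YTHDF2-ADAR 4547 genes at 21499 sites and YTHDF3-ADAR 7042 genes at 50789 sites. FOXK1, a transcription factor, had most sites in YTHDF1-ADAR cells, at 110, and ATP2B1, a plasma membrane calcium pump, had most in the others, at 101 and 117. ALYREF, an mRNA export adaptor, carried 90, 87 and 96 sites at 6.09%, 6.03% and 7.19% per site in polysome RNA, and SPTAN1, a spectrin, 99, 92 and 105 sites. The highest summed polysome scores were those of KIF5A, a neuronal kinesin, at 19.1, 12.7 and 28.7, or 66.0%, 74.5% and 57.3% per site. NDRG4, PPP3CA, PDE1B, ALDOC and SNAP25, genes of high expression in brain, were also among the top 10 of at least 1 line. KIF5A was measured at 19.4 CPM on average in the 4 libraries of YTHDF1-ADAR replicate 3 and YTHDF2-ADAR replicate 2 and at 30.1 CPM in the other 8 libraries of these lines, and PDE1B at 1.52 and 7.70 CPM.

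Most edited genes were edited slightly less on polysomes. The median editing per site was 2.01% in total and 1.83% in polysome RNA for YTHDF1-ADAR, 1.19% and 1.15% for YTHDF2-ADAR, and 1.76% and 1.45% for YTHDF3-ADAR. Among the 6381, 4276 and 6883 genes with both scores above 0, 64.2%, 60.2% and 66.9% had the lower value on polysomes. Another 477, 271 and 159 genes had a score missing or at 0 and are not in these shares. The authors called 59 genes higher and 86 lower for YTHDF1-ADAR, 19 and 44 for YTHDF2-ADAR, and 55 and 195 for YTHDF3-ADAR, or 2.11%, 1.39% and 3.55% of edited genes. Among the largest changes, HMGN5, a nucleosome-binding protein, went from 0.605% to 3.70% per site for YTHDF1-ADAR (authors' adjusted p = 5.66e-09), and UTP20, a factor in small ribosomal subunit assembly, from 0.238% to 4.80% for YTHDF3-ADAR (authors' adjusted p = 2.68e-05). KPNA6, an importin, went from 1.03% to 0.0464% for YTHDF1-ADAR, PLEKHA7, a cell junction protein, from 7.82% to 1.14% for YTHDF2-ADAR, and TIPARP, an ADP-ribosyltransferase, from 3.73% to 0.267% for YTHDF3-ADAR.

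The genes listed as edited in the 3 lines largely overlapped. Without a library that lacks a fusion, marks of the fusion proteins cannot be told from other editing that the lines share. In a background of 15161 tested protein-coding genes with a symbol, YTHDF2-ADAR and YTHDF1-ADAR shared 3972 edited genes (2027 expected, odds ratio 20.3), YTHDF3-ADAR and YTHDF1-ADAR 5287 (3134 expected, odds ratio 13.7), and YTHDF3-ADAR and YTHDF2-ADAR 4193 (2073 expected, odds ratio 37.7). Among the genes of highest expression the odds ratios were 10.9, 7.37 and 17.4 (2281, 2864 and 2359 shared against 1724, 2391 and 1748 expected), and at 10% editing per site or more 103, 45 and 102. The genes at 10% or more include some edited nearly completely in every line. CPLX2 stood at 99.1%, 99.2% and 96.2% per site in total RNA of YTHDF1-ADAR, YTHDF2-ADAR and YTHDF3-ADAR cells. Over all edited genes, 3817 were shared by the 3 lines out of 8714 edited in any, and 1353, 137 and 1308 were listed for YTHDF1-ADAR, YTHDF2-ADAR or YTHDF3-ADAR alone. Editing per site in total RNA had Spearman's rho of 0.55, 0.50 and 0.57 across the shared genes of the 3 pairs, and the change on polysomes 0.17, 0.21 and 0.13. Positions of the sites are not given, so sharing could be counted by gene only.

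Edited genes were compared on polysomes with unedited genes of the same expression. Their median log2 fold change was 0.149 for YTHDF1-ADAR, against 0.247 for the mean of 10000 random lists of unedited genes matched on expression, a difference of -0.098. The differences were -0.047 for YTHDF2-ADAR and -0.033 for YTHDF3-ADAR, each with p = 2e-04 by permutation with these random lists, the smallest two-sided value they can give. Matching on gene model length too left -0.082, -0.029 and -0.019, and matching on total RNA libraries left -0.087, -0.034 and -0.020 (p no higher than 4e-04 by the random-list test in each case). Without YTHDF3-ADAR polysome replicate 1 the difference in that line was -0.021. Without matching, edited genes lay above unedited genes, at 0.149 against 0.114, 0.146 against 0.114, and 0.075 against 0.015, and camera gave this upward direction with p = 0.128, 0.122 and 0.106, or 0.292, 0.272 and 0.188 with an estimated correlation. The sign thus turned with the matching. The edited genes were chosen on these same samples and are more highly expressed (median log2 CPM 5.35 against 2.80 for YTHDF1-ADAR), so the lists are not independent evidence.

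**Figure D4:**
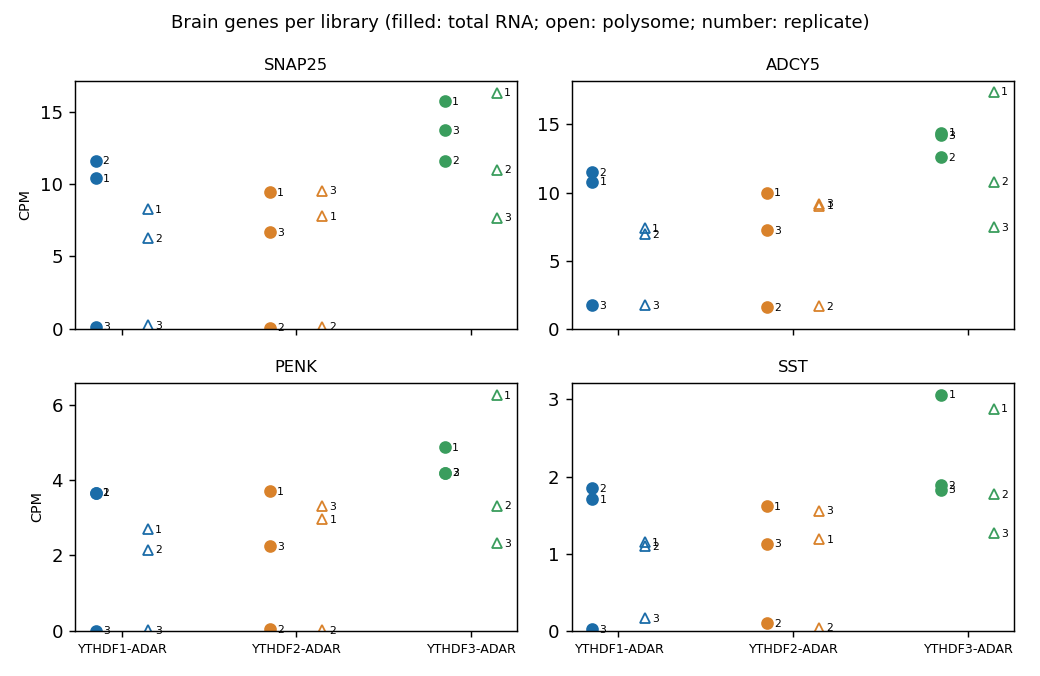
CPM per library (y axis) at SNAP25, ADCY5, PENK and SST by construct (x axis), with filled circles for total RNA, open triangles for polysome RNA and numbers for replicates. YTHDF1-ADAR replicate 3 and YTHDF2-ADAR replicate 2 were near 0 for SNAP25 in both fractions (mean 0.148 CPM over 4 libraries), against 8.74 in the other 8 libraries of these lines and 12.6 in YTHDF3-ADAR cells.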

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

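For the ribosomal protein pattern, the tests of scaling and of short mRNAs were chosen only after the result was seen. The count of library pairs below all others was fixed before. The set tests of the difference between lines and the permutation test of library pairs were not in the plan fixed beforehand. The row that does not name a human gene is named for a rat Apobec gene and stands outside the genes analysed. It held 40 counts over the 18 libraries, with 4 libraries above the 3 counts that a count of 0 allows, 5 libraries at 0 and a highest value of 8. YTHDF3-ADAR replicates 1, 2 and 3 held 8, 5 and 3 counts in total RNA and 2, 2 and 7 in polysome RNA. Those of YTHDF1-ADAR held 1, 0 and 0 in total RNA and 6, 2 and 1 in polysome RNA. Each YTHDF2-ADAR library held 0 or 1.

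Polysome association of cytosolic ribosomal protein mRNAs had a median difference of -0.73 (log2) between YTHDF3-ADAR and YTHDF1-ADAR cells and of -0.71 between YTHDF3-ADAR and YTHDF2-ADAR cells. The difference passed camera with the preset correlation (adjusted p = 5.83e-70 and 8.14e-62) and did not with an estimated correlation (adjusted p = 0.226 and 0.237 with an estimated correlation), nor by fry with the replicate block (adjusted p = 0.279 and 0.284). In a fit of the YTHDF3-ADAR libraries alone, edgeR called 1 of 78 ribosomal protein genes lower, against 60 in the fit of all 18 libraries, with medians of -0.63 and -0.65.

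Scaling of the libraries alone would have moved all protein-coding genes alike, but the ribosomal protein median lay 0.65 or more below theirs (-0.69 and -0.65). A loss of short mRNAs would have moved the 423 other protein-coding genes with a gene model of at most 999 bases, which bounds the length of their mRNAs, but their relative medians were -0.08 and -0.06 (bootstrap SE 0.02 and 0.01). Of the 3 YTHDF3-ADAR pairs, 2 lay below all 6 others and pair 1 did not (-0.07), so a state of single libraries and a property of the line cannot be told apart with 3 pairs. A lower translation of these mRNAs in YTHDF3-ADAR cells, or a difference in growth between cultures, may account for the pattern, and neither was tested.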

How the results depend on the processing

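The alternatives that left out library pairs or the genes low in 4 libraries, and the list medians under each scaling, were chosen after seeing the data, and the others before. In this part, 3 values are in the order YTHDF1-ADAR, YTHDF2-ADAR and YTHDF3-ADAR, and total RNA contrasts are YTHDF2-ADAR against YTHDF1-ADAR, YTHDF3-ADAR against YTHDF1-ADAR and YTHDF3-ADAR against YTHDF2-ADAR. A 2-fold threshold left 41, 14 and 74 genes higher and 1919, 1532 and 1701 lower on polysomes, and 165, 1734 and 2363 in total RNA. Without normalization factors 10894, 9093 and 6788 genes were higher and 1527, 1364 and 1668 lower, with 326 and 7314 in the first total RNA contrasts. With no filter 997 genes were higher in YTHDF2-ADAR cells, and with 1 CPM in 9 libraries 1170 in YTHDF1-ADAR and 939 in YTHDF2-ADAR cells. Among protein-coding genes alone 906, 505 and 1249 were higher and 1460, 1004 and 1531 lower, since fewer genes were tested. With the replicate block 5012, 4148 and 3640 were higher and 4831, 4010 and 5390 lower, and total RNA gave 75, 1767 and 2931, though numbers do not pair samples across lines. Fits of the compared libraries alone gave 3766 higher and 4088 lower in YTHDF2-ADAR cells, 0 and 219 in YTHDF3-ADAR cells, and 969, 347 and 1496 in total RNA. The count of 0 was from edgeR, beside 3224 by DESeq2 over all libraries. DESeq2 also gave 1 gene for the difference between YTHDF3-ADAR and YTHDF1-ADAR and 768 in the first total RNA contrast. Apart from the filters on genes, the cause was not tested.

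Without YTHDF3-ADAR pair 1, 4463 genes were higher in that line, 265 and 288 differed from YTHDF1-ADAR and YTHDF2-ADAR cells in polysome association, and 12632 and 13745 in total RNA. Without YTHDF1-ADAR pair 3 and YTHDF2-ADAR pair 2, 299, 145 and 1197 genes were higher, 1310 and 858 lower in the first lines, and total RNA gave 68, 806 and 1318. Leaving out 1 library, the counts higher ran from 1190 to 1866, 658 to 1401 and 886 to 3936, and the counts lower from 2082 to 2579, 1511 to 1877 and 1941 to 4090. The count higher in YTHDF1-ADAR cells moved over 1.5 times without any of its libraries but total RNA replicate 3 (total RNA replicates 1 and 2 left 1436 and 1370, polysome replicates 1 and 3 left 1617 and 1419). In YTHDF2-ADAR cells it did so without total RNA replicates 2 and 3 (818 and 658) or polysome replicates 1 and 3 (869 and 809), and the count lower without total RNA replicate 3 (1577) or polysome replicate 3 (1511). In YTHDF3-ADAR cells the count higher moved without total RNA replicates 1, 2 and 3 (3936, 1027 and 1350) and polysome replicate 2 (886), which also lowered the count lower to 1941, as YTHDF1-ADAR polysome replicate 2 did to 2082. The differences of polysome association ran from 0 to 0, 0 to 27 and 0 to 21 by edgeR, with the highest values without YTHDF3-ADAR polysome replicate 1, and 2 against YTHDF1-ADAR cells without YTHDF3-ADAR total RNA replicate 1. Total RNA ran from 232 to 325, 1644 to 10038 and 2514 to 11327, and moved over 1.5 times without any single library compared, except YTHDF2-ADAR replicate 1 in the last contrast. Edited genes ran from -0.109 to -0.088, -0.052 to -0.039 and -0.047 to -0.021, the last without YTHDF3-ADAR polysome replicate 1. Matched on expression and gene model length they gave -0.082, -0.029 and -0.019, and matched on total RNA libraries -0.087, -0.034 and -0.020.

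Shared edited genes numbered 127, 164 and 126 at 10% editing per site or more, and 2281, 2864 and 2359 among the genes of highest expression (above the 2/3 quantile), where fewer genes could be shared. Of 44 list calls on polysomes, 1 passed with an estimated correlation, while the replicate block, DESeq2 size factors and no filter kept all 44 and gave 48, 46 and 52 in all. Without the genes low in 4 libraries, the authors' editing calls were 59 higher and 84 lower, 18 and 44, and 55 and 195. Coverage minimums, other scales, a block and leaving out libraries could not be run for editing, nor sharing by position, since the tables hold 1 value per gene. In simulated data the tests found 20.9%, 64.2% and 98.5% of genes changed 1.5, 2 and 4-fold between fractions, 5.97%, 35.8% and 89.4% of those whose polysome association differed, and 31.3%, 67.2% and 100% in total RNA, with 5, 4 and 5 false calls among 26804 genes. Those data held no shifts shared by libraries, so neither the recovery nor the false calls need hold for the real libraries.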

Other observations

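The tests of brain marker shares, pseudogenes and strongly edited genes, and the KRAB tests by scores and over all genes, were chosen only after the result was seen, while the brain marker median, the KRAB test by mRNA level and the splits of 6 libraries were fixed before. The splits of library pairs were chosen after random shuffles of fractions had been seen to depend on the draw. The share of edited genes differed between lists, by a test that was not in the plan fixed beforehand. YTHDF1-ADAR, YTHDF2-ADAR and YTHDF3-ADAR had edited 21, 15 and 26 of 78 cytosolic ribosomal protein genes, against 43.1, 34.7 and 49.3 expected from random lists matched on expression (adjusted p = 0.00073, 0.0015 and 0.00073, permutation by random lists with Benjamini-Hochberg adjustment). Mitochondrial ribosomal protein genes were edited in 17, 14 and 21 of 64 cases (43.7, 30.0 and 42.9 expected), replication-dependent histones in 10, 7 and 14 of 52 (24.9, 19.2 and 27.3 expected), and replication and mitosis genes in 9, 6 and 10 of 34 (23.1, 17.4 and 23.5 expected). None of the 13 mitochondrially encoded mRNAs was edited in any line. The random lists were not matched on gene model length. The median model was 3208 bases for cytosolic ribosomal proteins and 510.5 for replication-dependent histones, against 4964 for all protein-coding genes. An effect of length on the share of edited genes was thus not separated. Proteasome genes were edited in 24, 23 and 29 of 31 cases (21.3, 16.3 and 21.8 expected), with adjusted p = 0.54, 0.049 and 0.011.

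A few editing changes were called by the authors for more than 1 protein. For YTHDF2-ADAR with YTHDF1-ADAR, YTHDF3-ADAR with YTHDF1-ADAR and YTHDF3-ADAR with YTHDF2-ADAR, 3, 1 and 1 genes were higher in both. That compares with 0.14, 0.29 and 0.13 expected if the calls were independent. Lower in both were 2, 3 and 1, with 0.52, 1.8 and 0.85 expected, and 1, 0 and 1 were called in opposite directions. NCL, which encodes nucleolin, was edited more on polysomes for YTHDF1-ADAR (odds ratio 4.52) and YTHDF2-ADAR (3.30), as was HMGN5 (6.31 and 4.69). HIPK3, a kinase (0.190 and 0.437), and SETD2, a histone methyltransferase (0.440 and 0.396), were edited less in pairs of lines. ADARB1 stood at 38.9, 247 and 1460 CPM in total RNA of YTHDF2-ADAR, YTHDF1-ADAR and YTHDF3-ADAR cells, where 4547, 6858 and 7042 genes were edited at 21499, 43036 and 50789 sites.

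Several brain genes with near-complete editing were low in 4 libraries. SNAP25, edited at 98.0% and 96.8% per site for YTHDF3-ADAR, stood at 0.148 CPM in YTHDF1-ADAR replicate 3 and YTHDF2-ADAR replicate 2 (both fractions), 8.74 in the other 8 libraries of these lines and 12.6 in YTHDF3-ADAR cells, and ADCY5, an adenylate cyclase, at 1.68, 9.01 and 12.8. In these 4 libraries 425 genes were at least 4-fold lower in both fractions and 0 were 4-fold higher. Of 59 genes edited at 50% or more 16 were among the lower genes, against 9 of 8632 other edited genes.

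The median log2 ratio of the 59 genes lay at -1.06 relative to other edited genes, but the 4 libraries were singled out by genes among them, so editing by the fusion protein stays open. Brain RNA from outside the cell line is a candidate source: 16 of 54 measured brain markers (29.6%) were 4-fold lower in both fractions, against 1.28% of measured genes (Fisher exact two-sided p = 5.32e-18; 16 of 53 without genes named for their editing). Of the other lists, 2 of 6 heart and muscle markers, 1 of 9 cerebellum markers and 0 of 4 liver markers were also 4-fold lower in both fractions. The 4 libraries were singled out by low brain genes, so the share of brain markers is not independent of their choice. The most abundant brain markers, NEFM, NEFL and MAP1B, stood at 580, 235 and 108 CPM in the 4 libraries themselves and at 521, 201 and 71.7 in the other 8. A test fixed before its result was seen went against this source by its highest value: it required medians under -1 and named values above -0.5 as contrary. The medians in total and polysome RNA were -0.98 and -1.04 (striatal), -0.64 and -0.41 (general neuron) and -0.54 and -0.14 (glial). Its controls, set to lie near 0, had medians of -0.82 in total and -0.09 in polysome RNA (6 heart and muscle markers) and of -0.24 and 0.35 (4 liver markers), at median levels of only 0.208 and 0.144 CPM. That limit was judged too strict only after the value was known, because the cells express many of these markers themselves (median 2.27 CPM in the 4 libraries, 34 of 54 at 1 CPM or more), which would hide a small share, so the marker median decides nothing. Processed pseudogenes were 2.62 times as frequent among the 425 genes as among measured genes, which RNA of another organism may also give, so none of these sources is settled.

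KRAB zinc finger genes were edited more often by YTHDF1-ADAR (41 of 101) than by YTHDF3-ADAR (11), with 31 edited by the first alone and 1 by the second alone (exact McNemar p = 1.54e-08, two-sided). The list was singled out by these same counts, and each line gives 1 list of edited genes over all replicates. The McNemar p-value is thus no independent test of a difference between constructs. Lower KRAB mRNA in YTHDF3-ADAR cells did not account for all of the excess, since among 53 genes that were not lower the ratio was 2.43 (17 against 7). The ratio was 3.73 over all 101 genes and 2.55 (28 against 11) among those with scores in both fractions, so scores in 1 fraction carried part of the excess but not all. Over all protein-coding genes it was 0.978, so more editing in general does not explain it. Other ZNF genes had a ratio of 1.61 (148 against 92). Random lists matched on expression held 34.8, 20.5 and 36.7 edited genes for YTHDF1-ADAR, YTHDF2-ADAR and YTHDF3-ADAR, against 41, 10 and 11 in the KRAB list. Adjusted p was 0.36, 0.017 and 0.00073 (permutation by random lists with Benjamini-Hochberg adjustment). The YTHDF1-ADAR count lay near its expected value and the other counts below theirs. The random lists were matched on expression alone. A preference of YTHDF1 for these mRNAs is thus neither shown nor excluded by these values, and it was not tested on other data.

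The same 6 libraries can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real splits of polysome and total RNA called 5674, 4223 and 5392 genes, each called by 1 of 10 splits, and the highest other splits called 0, 0 and 3454, the last setting YTHDF3-ADAR replicate 1 of both fractions with polysome replicate 2. For total RNA the real splits called 490, 4856 and 6113 genes and the highest others 0, 3274 and 3672, the latter 2 setting YTHDF3-ADAR replicates 2 and 3 with replicate 1 of another line. For the 3 differences of polysome association, the 6 pairs of polysome and total RNA were split into 3 and 3, again 10 ways, and all 10 called 0 genes by edgeR, the real one included, with 166, 877 and 801 genes at an unadjusted p under 0.05 and 0, 1 and 0 calls by DESeq2.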
